A study of Solanum lycopersicum with 12 samples.

How the data were processed

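RNA from 30 mg of ground young leaf or root was sequenced in 12 libraries, 3 in each of 4 groups set by tissue and spray, per the labels' protocols. The plants received PSI-475 at 2.5 mL per L or water, and saline irrigation of 50 mM NaCl (5.8 dS per m). Sampling took place 2 h after the end of the light period. Libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols. The submitters' processing notes name fastp, featureCounts and DESeq2, without versions or settings. The aligner, genome build, annotation and strand setting are not given in the sources used here. Where genes overlap or have near-identical copies, the counting could split their reads.

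The deposited table holds FPKM (fragments scaled to locus length and to the assigned fragments of the library), made by the authors, for 35976 loci. Of these, 33925 have identifiers of the tomato locus scheme, 1167 have non-coding RNA identifiers and 884 are numbered loci of neither kind. All 12 columns were mapped to samples by name. In every library 100% of the values were whole fragments, within a tolerance of 0.001, once lengths and totals had been recovered from the digits. Since lengths were set so that values became whole, this is only in part a check. A factor shared by all counts of a locus is lost, so some lengths and counts may be too small. The shortest recovered length among loci tested in both tissues was 6 bases. The recovered fragments summed to at least 99.99% of the totals, which ran from 17108347 to 22993130.

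Loci with a mean of at least 1 FPKM entered each test. The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) with a mean-variance trend, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Leaf and root were each fitted on their own 6 libraries. The interaction and the comparison of untreated tissues used all 12. Whole fragments were used for depth, shares and the limma-voom alternative. Pairs of replicates were compared by a chi-square test of their fragments. The statistic over its degrees of freedom ran from 2.28 to 18.9, so no pair agreed within sampling noise and all were kept.

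Planned lists of genes by function and planned salt response genes were to be found by name or description. The files do not pair identifiers with names, and 0 of the 35976 identifiers matched the RefSeq gene table for assembly SLM_r2.1, so these lists and genes were not evaluated. The rule for named loci, fixed before the data were examined, took the largest log2 rises and falls among called loci whose treated and untreated libraries did not overlap. The rule also asked for a description. With none, that condition was dropped, and the number named was reduced to 1 rise and 1 fall per tissue. The largest leaf rise belonged to a numbered locus and is not named, so the next was taken. By chance 10% of loci would not overlap between 3 libraries and 3, and 47.9% of tested loci did not in leaf and 79.2% in root.

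In place of the lists, loci were grouped after the data had been examined. Leaf-higher and root-higher loci differed by at least 2 on the log2 scale between untreated leaf and root with an adjusted p under 0.05, and shared loci by under 1. These sets were tested among all 19324 loci past the filter over the 12 libraries, so that the filter did not favour either tissue. Because sets and effects use the same untreated libraries, medians were also computed with sets from replicate 1 and effects against replicates 2 and 3. Sets by identifier kind, chromosome and length were tested among the loci of each tissue. Large falls were compared between sets among loci whose untreated level allows a fall of that size on the log2(FPKM + 1) scale, also within 10 bins of that level (Mantel-Haenszel odds ratio) and with split controls. Set tests used camera with a preset correlation, adjusted over 3 tissue sets and over 19 other sets per tissue, with an estimated correlation and fry beside it.

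The procedure was tested on simulated fragments with the real library sizes, the means of the untreated group and 200 changed loci. All loci of a tissue were given the same spread, the average over loci with at least 200 fragments. Loci or libraries with a larger spread were therefore not simulated. In the leaf simulation, with 18368 loci tested, 53.1% of 1.5-fold, 90% of 2-fold and 100% of 4-fold changes were recovered, and 12 of 133 calls were of unchanged loci. In the root simulation, with 17872 loci tested, the shares were 75.5%, 90% and 100%, and 9 of 145 calls were of unchanged loci. These are 9.02% and 6.21% of the calls, above the nominal 5%. Alternatives varied the pseudocount, filter, scaling, estimate of the spread, library weights, threshold, replicate block, libraries in the fit and each replicate left out. Figures were drawn with matplotlib 3.10.9.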

Results

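The series compared tomato plants (Solanum lycopersicum) sprayed with PSI-475, a biostimulant, with plants sprayed with water, in young leaf and in root. All 12 libraries came from plants irrigated with 50 mM NaCl, so the comparison is of treated with untreated plants under salinity. PSI-475 had been given as a foliar spray at 2.5 mL per L to plants 65 days old, 1 day before salinity began, and again 27 days into it. Tissue was taken at 127 days. Each of the 4 groups, untreated leaf, treated leaf, untreated root and treated root, held 3 libraries. The labels do not say whether the replicates came from separate plants, so p-values measure the spread between these libraries, which may be technical.

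The values were FPKM for 35976 loci, of which 8156 were at 0 in every library. Library totals, recovered from the FPKM values, ran from 18190465 to 22993130 fragments in leaf and from 17108347 to 20595008 in root. The files give locus identifiers and do not pair them with gene names, and none of the identifiers was found in the gene table used here. Groups of loci are therefore described by where they were expressed in untreated plants, and few single loci are named. Among loci with at least 200 fragments, the median coefficient of variation between replicates was 8.89% in untreated leaf, 6.26% in treated leaf, 4.14% in untreated root and 5.69% in treated root. The coefficient expected from sampling of fragments alone was 3.67%, 3.62%, 3.8% and 3.72%. A median of values taken from 3 libraries lies below such an expectation, so the comparison understates the excess over sampling. At the median locus the untreated root libraries were closest to counting noise. They still exceeded it, with a chi-square statistic over its degrees of freedom of 2.28 to 3.44 for their pairs.

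Tissue was the main difference between libraries. The first principal component held 82.5% of the variance and separated leaf from root, the second held 11.9% and separated treated from untreated root, and the third held 2.82% and separated treated from untreated leaf. Across the 19324 loci with a mean of at least 1 FPKM over all libraries, the mean Pearson correlation was 0.966 between untreated and treated leaf and 0.891 between untreated and treated root. Correlations within groups averaged 0.986 to 0.994. Treated roots correlated with untreated leaf at 0.641, against 0.576 for untreated roots. These correlations are across loci, which are not independent replicates.

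**Figure D1:**
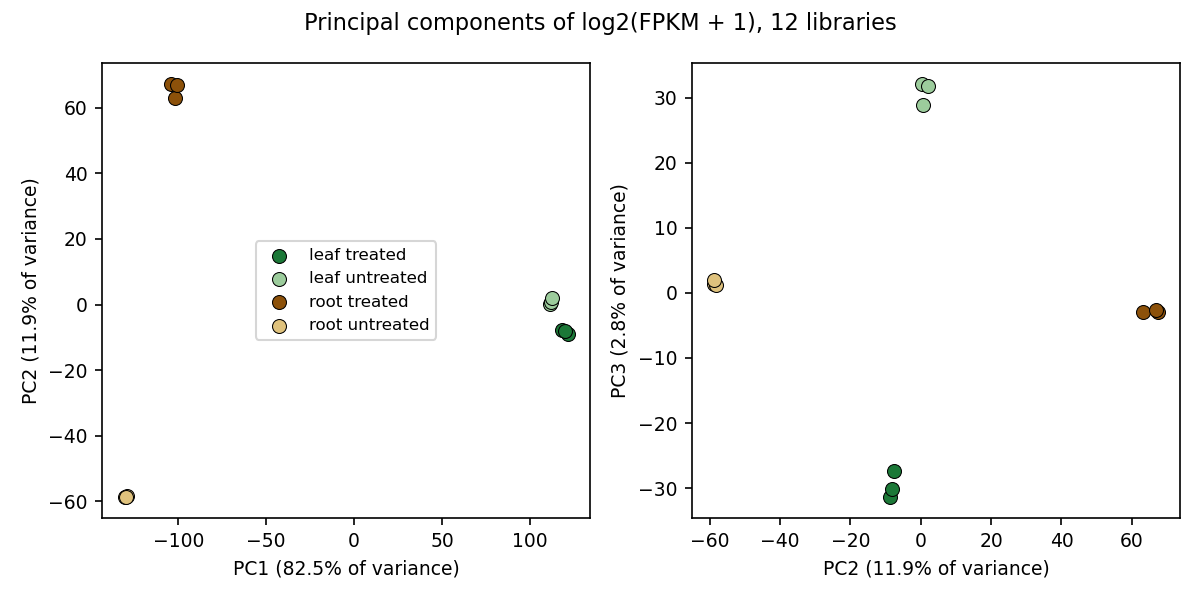
Principal components of log2(FPKM + 1) in the 12 libraries, each point 1 library coloured by group, with PC1 against PC2 on the left and PC2 against PC3 on the right (axes in component scores, with the percent of variance). PC1 (82.5%) separates leaf from root, PC2 (11.9%) the treated from the untreated roots, and PC3 (2.82%) the treated from the untreated leaves.

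Untreated root and untreated leaf were compared to describe the tissues and to form groups of loci. In limma, 6387 loci were higher in root and 9302 higher in leaf out of 19324. With median-of-ratios scaling the split was 7683 to 7883, and with quantile normalization 8060 to 7595. Loci at least 4-fold higher in untreated leaf formed the leaf-higher set of 2237 loci. Those at least 4-fold higher in untreated root formed the root-higher set of 1620 loci. A shared set of 11139 loci had log2 differences under 1. The root-higher loci held 26.8% ± 0.0152 (SD, n = 3) of the fragments of untreated root and 2.78% ± 0.0772 (SD, n = 3) of those of untreated leaf. The leaf-higher loci held 26.9% ± 0.176 (SD, n = 3) of the fragments of untreated leaf and 1.62% ± 0.0118 (SD, n = 3) of those of untreated root. The sets were chosen after the data had been examined.

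In leaf, the question was how the spray changed the transcriptome of young leaves under salinity. Changes were widespread but small, with a median absolute log2 change of 0.236 over all tested loci. The signed median, which measures the balance of rises and falls, was -0.09. In all, 2481 loci rose and 3464 fell out of 18405 tested (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 478 rose and 211 fell by at least 2-fold, and 67 rose and 12 fell by at least 4-fold, so the larger changes were mostly rises. Leaf-higher loci took a larger part of the treated leaf libraries, at 31.3% ± 0.740 (SD, n = 3) against 26.9% ± 0.176 (SD, n = 3). The shared loci took 46.3% ± 0.703 (SD, n = 3) against 51.0% ± 0.237 (SD, n = 3). For both shares the treated and untreated libraries did not overlap, and the 2-sided exact permutation p was 0.1, the smallest that 3 libraries against 3 allow.

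By set, 584 leaf-higher loci rose and 502 fell in leaf, 314 root-higher loci rose and 138 fell, and 813 shared loci rose and 1907 fell. The median log2 changes were 0.0033, 0.024 and -0.12. Against all other loci, camera with a preset correlation gave adjusted p = 0.0114 for the leaf-higher, 0.00011 for the root-higher and 0.00112 for the shared set. With an estimated correlation the adjusted p was 0.105 for the leaf-higher set, 0.0351 for the root-higher set and 0.105 for the shared set, so the root-higher set alone passed both tests. Only 980 of the 1620 root-higher loci reached 1 FPKM in untreated leaf. The rest cannot fall by 2-fold on this scale but can rise, so the floor may add to the excess of rises in this set. These medians depended on scaling. With median-of-ratios scaling they were 0.12, 0.076 and -0.010, and the leaf-higher median turned to -0.037 when the values were rescaled to TPM. Relative to the median of all loci, the leaf-higher set was at 0.083, the root-higher set at 0.104 and the shared set at -0.039 as deposited, and at 0.102, 0.058 and -0.028 with median-of-ratios scaling. Leaf-higher loci were over-represented at both ends of the leaf response. Among the 17881 loci with at least 1 FPKM in untreated leaf, which a 2-fold fall on this scale requires, they made up 92 of the 196 that fell by at least 2-fold, or 46.9% against 12.5% (odds ratio 6.41, 95% interval 4.77 to 8.6, Fisher's exact test across loci). Within 10 bins of untreated level the odds ratio was 4.89, and with sets and effects from separate untreated libraries it was 4.98. Among the 19324 loci, they made up 121 of the 457 that rose by at least 2-fold, or 26.5% against 11.6% (odds ratio 2.85, 95% interval 2.28 to 3.54). Root-higher loci were also over-represented among these rises, at 76 of the 457, or 16.6% against 8.38% (odds ratio 2.24, 95% interval 1.72 to 2.89). Shared loci were under-represented (odds ratio 0.343). Rises were not compared within bins of untreated level or with split controls.

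Among the largest leaf changes, Solyc07g064160.3 rose from 34.7 ± 1.14 to 618 ± 17.7 FPKM (SD, n = 3), a log2 change of 4.11 (SE 0.061, limma adjusted p = 3.92e-08). The same locus rose in root by 1.69 on the log2 scale (limma adjusted p = 1.36e-07), and the interaction test put the root effect below the leaf effect by -2.42 (limma adjusted p = 3.9e-10). The steepest fitted fall was that of Solyc10g017970.1, a short locus of 183 bases, with a log2 change of -3.61 (SE 0.96, limma adjusted p = 0.0226). It had 0 fragments in all 3 treated leaf libraries. Its untreated libraries were far apart, at 2.23, 6.61 and 73.2 FPKM, and without the third the untreated mean went from 27.3 to 4.42. Against a floor of 3 fragments per library it was at least 36.7-fold lower in treated leaf, and at least 5.93-fold lower without that library. Leaving out any 1 treated leaf library ended the call, with limma adjusted p from 0.0589 to 0.0637.

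The balance of rises and falls in leaf depended on scaling. With median-of-ratios scaling 3287 loci rose and 1819 fell, 64.4% rises against 41.7% as deposited, and the median log2 change went from -0.09 to 0.023. The number of calls was 3940 without treated leaf replicate 1 and 3715 without treated leaf replicate 3, against 5945 with all libraries.

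In root, the question was whether a spray on the leaves was accompanied by changes below ground. The response was much larger: 9511 loci rose and 4486 fell out of 18277 tested (limma, adjusted p under 0.05). By at least 2-fold, 2251 rose and 1856 fell. By at least 8-fold, 20 rose and 173 fell. Root-higher loci fell as a group: 1134 of the 1620 fell and 345 rose, with a median log2 change of -1.12 (quartiles -2.04 and 0.011). Their part of the root libraries went from 26.8% ± 0.0152 (SD, n = 3) to 14% ± 0.287 (SD, n = 3).

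Leaf-higher loci moved the other way in root. Of 2237, 1189 rose and 144 fell, with a median log2 change of 0.40, and their part of the root libraries went from 1.62% ± 0.0118 (SD, n = 3) to 3.05% ± 0.0261 (SD, n = 3). Only 1252 of the 2237 reached 1 FPKM in untreated root. The rest cannot fall by 2-fold on the log2(FPKM + 1) scale but can rise, so the floor may add to the count of rises over falls. Of the 11139 shared loci, 5918 rose and 1929 fell, and their part went from 50.8% ± 0.036 (SD, n = 3) to 62.5% ± 0.392 (SD, n = 3). For each of these shares the 2-sided exact permutation p was 0.1, the smallest possible. In camera, the adjusted p was 1.9e-31 for the root-higher, 0.00221 for the leaf-higher and 0.00469 for the shared set. With an estimated correlation the adjusted p was 0.00643, 0.0399 and 0.00828, so all 3 calls held. Each set was compared with all other loci, which include the other sets, so these calls are not independent of each other. With sets formed from untreated replicate 1 and effects taken against the other replicates, the medians were -1.07, 0.386 and 0.273. Because a scaling moved the median of all root loci by over 0.1, changes are also given relative to that median. Relative to all loci the root-higher set was at -1.36, the leaf-higher set at 0.157 and the shared set at 0.030. With median-of-ratios scaling these were -1.41, 0.204 and 0.0086, and the call on the shared set was lost (adjusted p = 0.372 in camera).

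**Figure D2:**
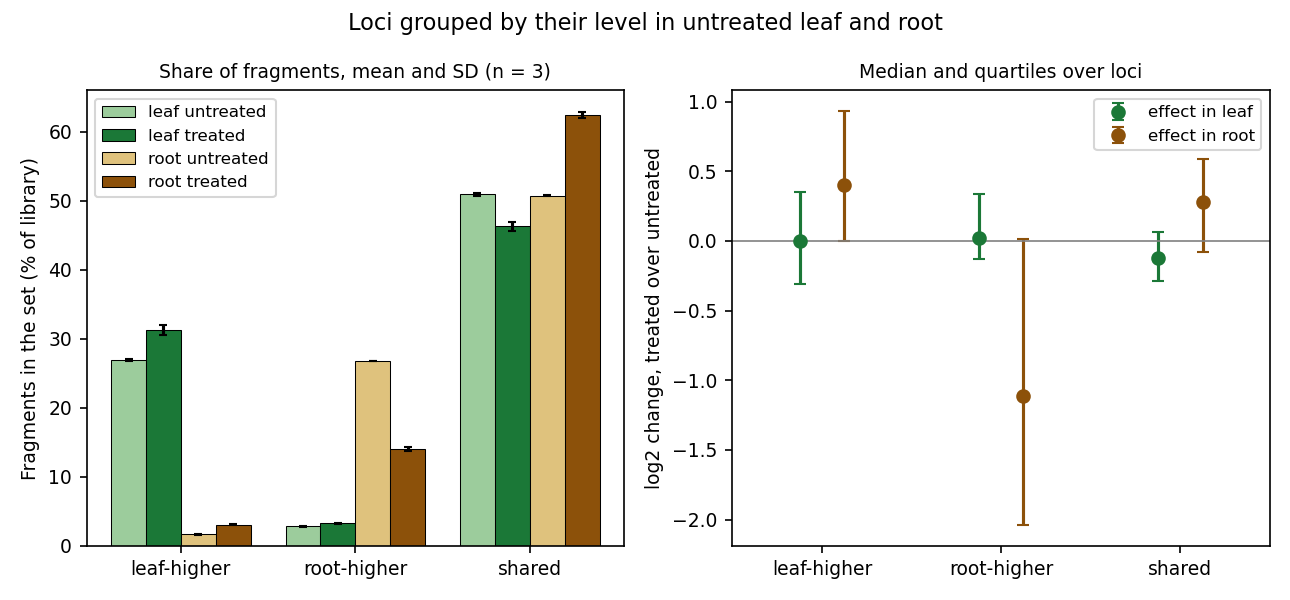
Left, percent of each library's fragments in leaf-higher, root-higher and shared loci (bars, mean; error bars, SD of 3 libraries). Right, log2 change of treated over untreated (points, median over loci; bars, quartiles) in leaf and in root. Root-higher loci went from 26.8% to 14% of root fragments, with a median log2 change of -1.12.

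The falls of at least 4-fold in root were mostly of root-higher loci. Among loci with at least 1 FPKM in untreated root, they made up 863 of the 1753 falls of at least 2-fold. This was 49.2% against 9.42% (odds ratio 18.8). Among the 14038 loci with at least 3 FPKM in untreated root, which a 4-fold fall on this scale requires, they made up 423 of the 551 that fell by at least 4-fold, or 76.8% against 11.5% (odds ratio 33.9, 95% interval 27.5 to 42.0, Fisher's exact test across loci). Within 10 bins of untreated level the odds ratio was 23.4, and with sets and effects from separate untreated libraries it was 30.2. Among the 10393 loci with at least 7 FPKM in untreated root, 173 fell by at least 8-fold. Of these, 152 were among the 1405 root-higher loci at that level and 0 among the 361 leaf-higher ones. Among rises the part of root-higher loci varied with the size of the change. They were 8.80% of the 2194 loci that rose by at least 2-fold, against 8.38% of the loci tested (odds ratio 1.06, 95% interval 0.902 to 1.24). Of 248 that rose by at least 4-fold, 51 were root-higher, or 20.6% (odds ratio 2.89, 95% interval 2.07 to 3.97), and of 20 that rose by at least 8-fold, 2 were (odds ratio 1.21, 95% interval 0.137 to 5.08). Over rises of any size, 21.3% of root-higher loci rose, against 53.2% of leaf-higher and 53.1% of shared loci. Of the 248 loci, another 59 were leaf-higher (odds ratio 2.42, 95% interval 1.77 to 3.27), and 69 were shared (odds ratio 0.279, 95% interval 0.208 to 0.371). As in leaf, rises in root were not compared within bins of untreated level or with split controls.

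Loci with non-coding RNA identifiers also fell on balance in root. Of 163 tested, 16 rose and 41 fell, with a median log2 change of -0.31 (adjusted p = 0.00162 in camera). This call was lost with an estimated correlation (adjusted p = 0.216). These loci had a median length of 112 bases. No chromosome passed the set test in either tissue, with camera adjusted p from 0.384 upward in root.

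Solyc04g051360.3 had the steepest fall in root, from 229 ± 1.72 to 0.249 ± 0.178 FPKM (SD, n = 3), a log2 change of -7.53 (SE 0.096, limma adjusted p = 1.11e-09). In leaf its log2 change was -0.041 (limma adjusted p = 0.917), and the interaction test gave a difference of -7.49 (limma adjusted p = 8.44e-10). Solyc03g071857.1 had the steepest rise, from 0.404 ± 0.262 to 43.5 ± 8.91 FPKM (SD, n = 3), a log2 change of 4.98 (SE 0.18, limma adjusted p = 8.8e-08). The untreated value rests on 3 to 11 fragments per library. The fitted changes are on the log2(FPKM + 1) scale, which understates the change of low loci.

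The excess of rises in root depended on scaling. With median-of-ratios scaling 6849 loci rose and 6137 fell, 52.7% rises against 68.0% as deposited, and 1407 rose and 2392 fell by at least 2-fold. The median log2 change over all tested root loci went from 0.28 to 0.047.

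The treatment effect differed between the tissues. In the interaction test, 9008 loci had a higher effect in root than in leaf and 4014 a lower one, out of 19324 (limma, adjusted p under 0.05). With median-of-ratios scaling the split was 5684 to 5841, and with quantile normalization 6994 to 4931. Among the 11269 loci past this test that were tested in both tissues, 81.4% had the larger change in root. Of these, 2715 were called in both tissues in opposite directions and 838 in the same direction. Opposite calls all but ensure a difference: all 2715 loci so called passed, against 838 of the 1548 called in the same direction. The ratio of 2715 to 838 therefore follows largely from the interaction test itself.

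Loci called in both tissues changed in opposite directions more often than independent lists would. Of the 16272 loci tested in both, 2039 fell in leaf and rose in root, against 1702 for independent lists (odds ratio 1.73, 95% interval 1.59 to 1.87). Another 676 rose in leaf and fell in root, against 443 (odds ratio 1.99, 95% interval 1.80 to 2.21). By contrast, 916 rose in both against 1030 (odds ratio 0.763), and 632 fell in both against 732 (odds ratio 0.795). Each was tested with Fisher's exact test across loci, which are not independent replicates. The counts depended on scaling. With median-of-ratios scaling 787 loci fell in leaf and rose in root against 619 (odds ratio 1.60), 1074 rose in leaf and fell in root against 860 (odds ratio 1.53), 1031 rose in both against 1006 (odds ratio 1.05) and 479 fell in both against 529 (odds ratio 0.853). Across loci the leaf and root effects were nearly unrelated, with r = -0.0896 and rho = -0.0826.

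**Figure D3:**
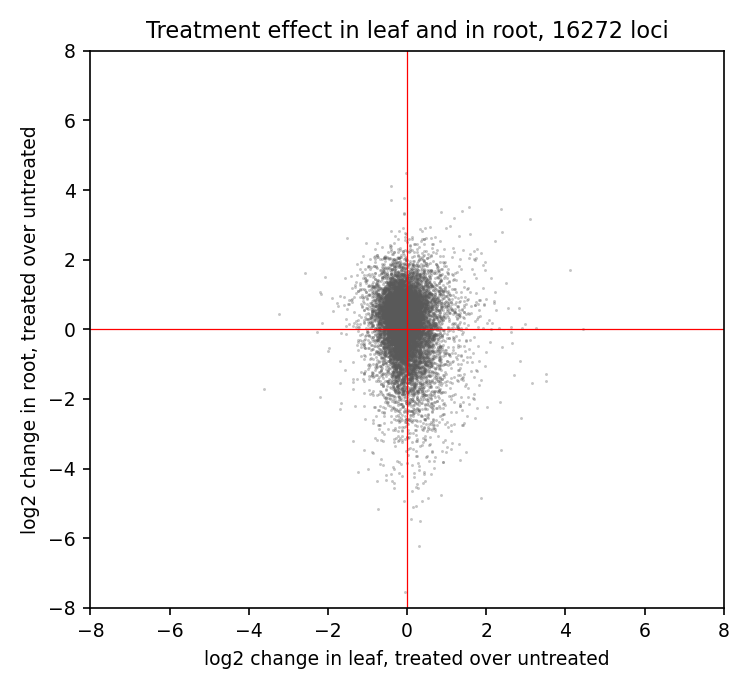
log2 change of treated over untreated in leaf (horizontal axis) and in root (vertical axis), each point 1 of the 16272 loci tested in both tissues. The cloud is wider along the root axis, with an SD 2.08 times that in leaf, and shows almost no common trend (r = -0.0896).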

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

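The tests of abundant leaf loci, of loci of similar length, of the root-higher loci within the library total and of the splits that kept the grouping of 1 tissue were chosen only after the results had been seen. The treatment effect differed between root and leaf at 13022 loci in the limma interaction test. Of these, 2715 were called in opposite directions in the separate tissue tests, which is every locus so called, since opposite calls all but ensure a difference. Other splits were drawn to ask whether chance could give as many. Of 100 splits of the treatment labels within tissues, out of 200 possible, 1 gave as many loci, the real one, and the highest other gave 11436, so chance can be excluded among these libraries only for the case that neither tissue responded. The high counts follow the root libraries: the 13 other splits that kept the real root grouping called 8732 to 11436 loci, and the remaining 86 at most 409. A difference between tissues needs the splits that keep the real grouping of 1 tissue, and these are 20 for root and 20 for leaf, too few for a share under 0.05. In both the real split called 13022 loci and the highest other 11436. Both families also hold the split that keeps both real groupings and swaps the labels in 1 tissue. That split tests the sum of the effects in leaf and root and is not a regrouping of libraries. The value of 11436, the highest in both families, may belong to it, which was not checked.

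For the comparisons within 6 libraries, 10 splits are too few for a share under 0.05. In leaf the real split called 5945 loci and the highest of the others 0. In root these were 13997 and 0, and for untreated root against untreated leaf 15689 and 0. In each case 1 of the 10 splits, the real one, gave as many loci.

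Treated roots had lower levels of root-higher loci and higher levels of leaf-higher loci. Leaf RNA in the treated root libraries would need a share of 56.5% for the median fall of the 1620 root-higher loci. By contrast, 59 abundant leaf loci, little expressed in untreated root, implied at most 1.00% and a median of 0.0417%. This argues against leaf RNA as the source of that fall. The share that the rise of leaf-higher loci would need was not computed. The test set in advance, a ratio of percentiles of the implied share over 89 leaf loci, could not be formed, since the 25th percentile was -0.0869%, and it decides nothing. Gene length was argued against by loci of similar length. In 10 bins of length the gap between the medians of the 2 sets was 1.21 to 1.83, against 1.52 over all loci, so the lowest was 79.9% of it. Removing the trend with length left 99.8% of the gap, but that trend spanned 0.18 from its 5th to its 95th percentile, too little to remove the gap, so this decides nothing. Noise between libraries in the shared untreated roots was argued against. The covariance of the root effect with the leaf minus root difference was 0.689, and 0.678 with split controls. In 100 simulations of unchanged roots it was at most 0.0119. Both checks use the spread between these libraries, which may be technical, so a deviation common to all untreated root libraries could not be detected. An effect of the treatment on root transcripts may underlie the pattern, as a hypothesis, and a difference in which part or age of root was sampled, or in RNA from other organs, was not tested.

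More loci rose than fell in root. The 10 most abundant loci do not account for it, as leaving them out of the library totals removed 1.2% of the median log2 change. Whether the excess comes from the scaling of FPKM to the library total cannot be told apart from a rise of most loci. With median-of-ratios scaling the share of rises was 52.7%, but that scaling centres the typical locus near no change, so the value decides nothing. Leaving the root-higher loci out of the totals removed 71.9%, taking the median from 0.28 to 0.078, which a fall of these loci or a rise of all others would both give, since the values are relative.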

How the results depend on the processing

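Tests on scaling and on replicates left out of the untreated tissue comparison, on scaling of the overlap, limma-voom and all tests on tissue sets were chosen after the data had been examined. Counts of rises or of falls alone moved further with scaling than their totals did. With median-of-ratios scaling, falls in leaf went from 3464 to 1819. Loci with a higher effect in root than in leaf went from 9008 to 5684. Total counts of called loci stayed within 1.5 times under the alternatives run, except as follows. Requiring at least 2-fold gave 689 loci in leaf, 4107 in root and 5325 in the interaction, by a stricter rule. Leaving out 1 replicate gave 3715 to 6518 loci in leaf, with 3940 without treated replicate 1 and 3715 without treated replicate 3, and the cause was not tested. It gave 13241 to 13764 in root, 12447 to 13385 in the interaction and 15092 to 15566 between untreated tissues. The median log2 change of shared loci in root lost its call with median-of-ratios scaling (0.0465, camera adjusted p = 0.372) and quantile normalization (0.113, adjusted p = 0.121), which remove most of the overall shift, while its adjusted p under the other alternatives was at most 0.00971 with split controls. The median of leaf-higher loci in leaf, near 0, went to 0.120 with median-of-ratios scaling and changed sign when rescaled to TPM (-0.0374) and without untreated replicate 3 (-0.00124) or treated replicate 3 (-0.0044), with a range of -0.0044 to 0.0115 over the replicates left out. That of shared loci in leaf went from -0.12 to -0.0103 with median-of-ratios scaling. Of 152 values of single loci under alternatives, 148 kept direction and side of the threshold, 4 lost the call, all of Solyc10g017970.1, and 0 reversed. With a replicate block 4494 loci were called in leaf, 13869 in root and 12785 in the interaction. Pairing by replicate number was looked for in the deviations of each library from its group mean. For same-numbered libraries of different groups these deviations correlated at -0.238 to 0.0938. In 0 pairs of groups did every library correlate best with its own number. No sign of pairing was seen, which 3 libraries per group cannot exclude. The settings listed for the gene lists were not run, since the lists could not be matched. Depth limits loci with few fragments, and the simulations recovered 4% of the smallest changes drawn in leaf and 18.8% in root.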

Other observations

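Neighbouring loci changed together in both tissues. Loci were ordered by their number along each chromosome, as the tomato identifiers give it. In root, 65.3% of 10654 adjacent pairs with both members called changed in the same direction, against at most 58.3% in 1000 permutations of loci within chromosomes. In leaf the share was 61.7% of 2065 pairs, against at most 55.7%. The permutation p was 0.001 in both tissues, the smallest that 1000 permutations can give. The excess reached large changes: 91 adjacent pairs in root changed by over 2 on the log2 scale in the same direction, against a mean of 20.7 and at most 35 in the permutations. In leaf there were 6 such pairs, against at most 3. Tandem copies of a gene may respond alike or share reads, and coordinates and sequences that would separate these were not used here.

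Some loci went from expressed to undetected or the reverse. In root, 8 loci had at least 30 fragments in every untreated library and 0 in every treated one, and 3 loci the reverse. Of these, 4 of the 8 and 2 of the 3 were numbered loci, a kind that makes up 884 of the 35976 loci. That total includes 8156 loci at 0 in every library, which cannot meet this rule. Among the 18277 loci tested in root, 546 were numbered loci. In leaf there were 0 of either kind.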
